A study of Mus musculus with 5 samples.

How the data were processed

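RNA sequencing had been done on hearts of C57BL/6 mice carrying a calcineurin transgene under the alpha myosin heavy chain promoter, a model of severe cardiac hypertrophy. Per the labels, the mice were given vehicle or JIB-04, a small molecule inhibitor of Jumonji histone demethylases, with JIB-04 at a dose of 50 mg/kg. Dosing began at an age of 4 weeks with 3 doses each week, and hearts were taken at postnatal day 158. The title of JIB-04 replicate 3 spells the genotype abbreviation with a letter different from the other titles. Its genotype label is the same, and it was taken as calcineurin transgenic, with Ppp3ca at 5421 CPM against 4341 to 8022 CPM in the others. The labels placed 2 libraries in the vehicle group and 3 in the JIB-04 group. They gave no sex, litter, cage, sequencing batch or date, so no batch could be examined. The labels do not say in words that each library came from a separate animal. The p-values of single genes measure only the spread between these libraries.

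RNA was extracted with Trizol and libraries were made with a stranded mRNA kit, per the labels' protocols. FastQC 0.11.2, TopHat2 2.0.12, Picard 1.127, featureCounts, Subread and edgeR, with genome build mm10, are named in the submitters' processing notes without a stated role or order. The deposited files give 1 value per gene and library in a column whose header reads CPM, the usual unit of reads scaled by library size. These deposited values were treated as a normalised signal, not as plain CPM, because the columns summed to between 954981 and 1046902. The authors had therefore divided by a library size times a normalisation factor, as far as the values show. Each value was a whole multiple of the value of 1 read in its library, so whole reads were recovered. All values (100%) lay within 0.01 of a whole number, with a largest deviation of 0.00018. The recovered totals were 32152168 to 37002846 reads per library. The value of 3 reads was 0.0804 to 0.0977 CPM, which sets the lowest level that could be seen, for counting error only.

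The files held 19061 gene rows and 1 blank row, and 266 genes had no read in any library. Genes with too few recovered reads were removed with edgeR's filterByExpr, a minimum of 10 reads in libraries of middling size and of 15 in total, which left 14414 genes. There were no rows on the mitochondrial chromosome. Of the gene names, 26 looked like calendar dates, a spreadsheet conversion, and none of these is named in the text. Rows that shared identical values with another row at 100 or more reads numbered 43, and such rows cannot be told apart. Among them were the pairs Hba-a1 and Hba-a2, Hbb-b1 and Hbb-bs, and Hbb-b2 and Hbb-bt, while Hbb-b1 and Hbb-b2 had different values. Of the symbols, 17918 matched a RefSeq annotation of the mouse genome, and 17857 of these overlapped it at the same place. Coordinates are given as in the files, on mm10.

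The comparison was JIB-04 against vehicle. A count test (edgeR quasi-likelihood) had been fixed as the main test before the data were examined, with limma on log2(value + 1) as the stated replacement should the files hold normalised values. They did, so limma (3.58.1, in R 4.3.3) with a mean-variance trend was the main test, on log2(CPM + 1), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A log2 fold change here is on the log2(CPM + 1) scale, which understates the change of genes at low CPM. The fit had 3 residual degrees of freedom. edgeR (4.0.16) on the recovered reads, limma-voom and DESeq2 (1.42.0) were alternatives. All of these tools were run side by side before the text was written, and the count of each is given.

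Before the data were examined, 40 gene lists were fixed. Of these, 37 had at least 5 genes tested. The 3 others were mitochondrially encoded genes (0 members tested), replication dependent histone genes (3) and sex linked genes (2). Lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the 37 lists. At this setting its p-values rest on the spread over genes, not on the spread between libraries. The alternatives were camera with the correlation estimated for each list, fry and cameraPR. List means per library were compared over the 10 ways to split 5 libraries into 2 and 3, where the smallest exact p is 0.1. After the single-gene results were seen, 4 more lists were added, for MHC class I, MHC class II, glucocorticoid receptor targets and platelets, and these appear only among the closing observations.

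Genes were named by a rule fixed beforehand. In each direction it took 10 genes, those with the smallest p where fewer passed. These came only from genes with a curated symbol and a mean CPM of at least 1. Every JIB-04 library also had to lie on the same side of both vehicle libraries. The rule also took up to 4 members with the smallest adjusted p from each list, and 23 genes fixed by name, of which 22 were tested. The rule gave 180 entries. The part of these that the text names was picked after the values were seen, and the genes outside the rule are said to be so. Further alternatives were other scalings, other filters on low values, a robust fit, other thresholds, omission of 5 technical lists, the replicate number as a block, and each library left out in turn. Pseudocounts of 0.25 and 4, the edgeR test on recovered reads and DESeq2 on the genes limma tested were added after the data were seen.

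The steps were tested on simulated data, with counts drawn for the 14414 genes from the real means, library sizes and dispersions, independently for each gene. For JIB-04 against vehicle, limma recovered 81% of 100 genes changed 2-fold and 90% of 100 changed 4-fold, with 18 false calls, which was 9.09% of its calls and above the nominal share. With edgeR these were 79% and 91%, with 29 false calls (13.9%). A list shifted by 0.5 on the log2 scale was called, and 0 of the 36 others were. Since the simulated genes varied independently, that says nothing about lists whose genes vary together. The shares of single genes recovered hold for the simulated setting only. They do not give the share of real changes that the fit would find.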

Results

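Hearts of calcineurin transgenic mice were profiled by RNA sequencing at postnatal day 158, after vehicle (2 libraries) or JIB-04 (3 libraries). JIB-04 inhibits Jumonji demethylases, enzymes that remove methyl groups from histones. The comparison asks how long-term dosing with the inhibitor altered the transcriptome of the hypertrophic heart. Depth was similar in the libraries, at 37002846 and 32152168 recovered reads for vehicle and 33629722, 35650602 and 34782448 for JIB-04. Values are deposited CPM, given as mean ± SD, with n = 2 for vehicle and n = 3 for JIB-04.

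With JIB-04, lists of interferon stimulated, inflammatory and macrophage genes rose relative to other genes, and lists of red blood cell, mitochondrial and cardiomyocyte genes fell. The interferon stimulated genes had a median log2 fold change of 0.51 and the macrophage and monocyte markers of 0.65, while the red blood cell markers fell by a median of 1.22 on the log2 scale. In total 18 of 37 lists passed camera at its preset correlation, 8 higher and 10 lower. None of the 18 passed when the correlation was estimated from the data (smallest adjusted p = 0.785 with an estimated correlation), and fry called 0 lists (smallest adjusted p = 0.398). At an unadjusted p under 0.05, 1 list passed camera with an estimated correlation and 2 passed fry. The list calls therefore depend on camera's preset setting. There the correlation was set to 0.01, while the estimates for the 18 lists ran from 0.0955 (atrial myocyte markers) to 0.966 (red blood cell markers). The preset p-values also rest on the spread over genes, not on the spread between libraries. How much of the loss is due to the correlation alone was not tested.

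No single gene passed limma's threshold in either direction. The smallest adjusted p was 0.316, and 566 genes were higher and 362 lower at an unadjusted p under 0.05, 928 together where 721 would be found by chance. edgeR and limma-voom also called 0 genes, with 946 and 872 at an unadjusted p under 0.05. DESeq2, which tested 15153 genes against 14414 with limma, called 69 genes higher and 16 lower, or 67 and 16 on limma's 14414 genes (a test chosen after the data were seen). All of its 85 first calls had every JIB-04 library on the same side of both vehicle libraries. A small p itself favours such genes, so this is no separate support for the calls. Of all 14414 genes, 10.7% had every JIB-04 library above both vehicle libraries and 12% below, where chance gives 10% each. Without JIB-04 replicate 1, limma called 27 genes higher and 2 lower.

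The 10 genes with positive values that the naming rule gave did not pass limma's threshold. They had the smallest p among named genes whose JIB-04 libraries all lay above both vehicle libraries. Cd72, a receptor of B cells and some myeloid cells (chromosome 4, 43447723 to 43454626), had 1.16 ± 0.07 CPM in vehicle and 4.39 ± 0.72 in JIB-04, a log2 fold change of 1.31 with an SE of 0.14 (limma adjusted p = 0.316). Zbp1, a sensor of nucleic acids, had 1.04 ± 0.05 and 2.97 ± 0.17 CPM, and Slfn8 of the schlafen family 2.30 ± 0.10 and 5.21 ± 0.19 CPM. Ptprc, which encodes the leukocyte antigen CD45, had 7.46 ± 0.24 and 15.1 ± 2.2 CPM. H2-K1, a heavy chain of MHC class I, had 99.2 ± 1.2 and 133 ± 6 CPM. The other 5 were Lgals3bp, Slamf9, Oasl2, Ifi204 and Aoah, with log2 fold changes of 0.76, 0.77, 0.83, 0.76 and 0.69. DESeq2 called all of these 10 genes higher.

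The genes with negative values were picked by the same rule, from those with every JIB-04 library below both vehicle libraries. Setdb2, a member of a histone lysine methyltransferase family (chromosome 14, from 59402010), had 12.7 ± 0.4 CPM in vehicle and 6.86 ± 0.70 in JIB-04, a log2 fold change of -0.80 with an SE of 0.11 (limma adjusted p = 0.371). Fkbp5, a co-chaperone of the glucocorticoid receptor, had 109 ± 3 and 55.3 ± 11.9 CPM. Kcna5, a voltage-gated potassium channel, had 8.79 ± 0.04 and 5.68 ± 0.15 CPM. Timp4, an inhibitor of matrix metalloproteinases, had 4.19 ± 0.84 and 1.60 ± 0.42 CPM, and Hif3a, a hypoxia inducible factor subunit, 3.32 ± 0.51 and 1.38 ± 0.34 CPM. The other 5 were Tuft1, Rasgrp2, Ablim3, St3gal5 and Fam107a, with log2 fold changes of -0.73, -0.54, -0.44, -0.35 and -1.11. DESeq2 called all of these 10 genes lower.

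**Figure D1:**
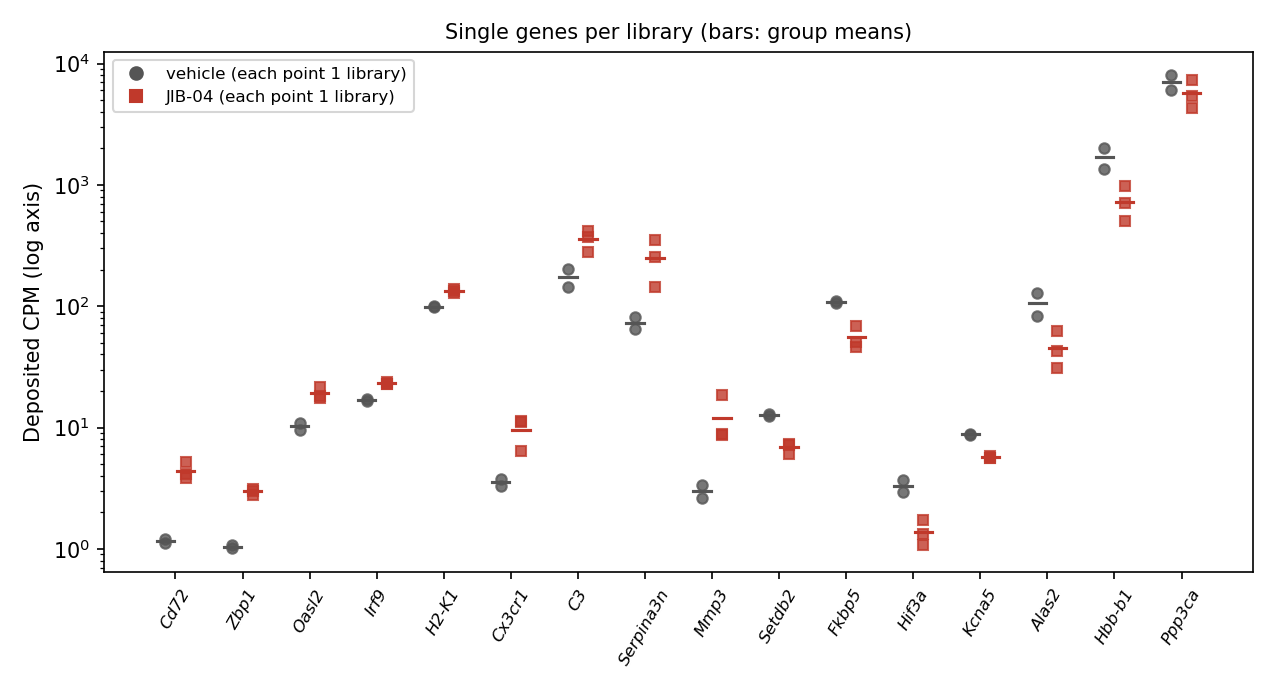
Deposited CPM of 16 genes on a log axis, with 1 point per library, circles for vehicle (n = 2), squares for JIB-04 (n = 3) and bars at group means. The groups do not overlap for any gene shown except Ppp3ca, for which vehicle was at 6082 and 8022 CPM and JIB-04 at 7275, 4341 and 5421 CPM. For genes picked by the smallest p in each direction, the lack of overlap was a condition of the pick. None passed limma's threshold.

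Reads on Ppp3ca, which encodes calcineurin A and can take up transgene reads, were high in every library. They were at 6082 and 8022 CPM in vehicle and at 7275, 4341 and 5421 CPM in JIB-04, and the log2 fold change was -0.33 with an SE of 0.29 (limma adjusted p = 0.862), -0.13 without vehicle replicate 2 and -0.53 without vehicle replicate 1. Xist, transcribed from the inactive X chromosome, was at 251 to 274 CPM in all 5 libraries.

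The interferon stimulated genes rose as a list (camera adjusted p = 4.41e-26; adjusted p = 0.785 with an estimated correlation). Of 31 members, 30 had positive values and 24 were higher in every JIB-04 library than in both vehicle libraries, where chance gives 10%. None passed over all genes, and 22 passed when adjusted over the list alone, all of them higher. Irf9, a subunit of the transcription factor that acts downstream of type I interferon, had 16.8 ± 0.5 CPM in vehicle and 23.1 ± 0.7 in JIB-04. Psmb8, a subunit of the immunoproteasome, had 8.22 ± 0.34 and 12.5 ± 0.5 CPM. Oasl2, an oligoadenylate synthetase family member, had 10.3 ± 1.0 and 19.1 ± 2.2 CPM. The member with a negative value, singled out after the values were seen, was Isg20, an exonuclease, at 9.17 ± 2.47 and 5.78 ± 1.83 CPM. List means, relative to the vehicle mean on the log2 scale, were 0.59, 0.48 and 0.39 in JIB-04 replicates 1, 2 and 3 and within 0.08 of 0 in vehicle (exact p = 0.1, the smallest that 10 splits allow). By the same splits the exact p was 0.1 for the list of proteasome, ubiquitin and autophagy genes. It was 0.2 for macrophage, inflammatory, red blood cell, lymphocyte and ribosomal genes, and 0.3 to 0.7 for the other called lists.

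Inflammatory cytokine and complement genes also rose as a list (median log2 fold change 0.51, camera adjusted p = 7.75e-19; adjusted p = 0.785 with an estimated correlation). None of 36 members passed over all genes and 12 passed adjusted over the list alone. C3, the central complement component, had 174 ± 43 CPM in vehicle and 356 ± 71 in JIB-04, and Serpina3n, an acute phase serine protease inhibitor, 73.3 ± 11.8 and 248 ± 102 CPM. Vcam1, an adhesion molecule for leukocytes, had 21.4 ± 0.5 and 30.7 ± 3.1 CPM. The macrophage and monocyte markers rose as a list (median 0.65, camera adjusted p = 2.69e-17; adjusted p = 0.785 with an estimated correlation), with 26 of 27 values positive, 0 past the threshold over all genes and 11 adjusted over the list alone. Cx3cr1, the fractalkine receptor, had 3.56 ± 0.33 and 9.61 ± 2.77 CPM. Emr1, which encodes the macrophage antigen F4/80, had 9.39 ± 2.87 and 18.7 ± 3.3 CPM. The median of these markers was 0.39 without vehicle replicate 2. With their mean as a covariate (a test chosen after the result was seen), the median of inflammatory genes was 0.03. That mean was itself higher in every JIB-04 library than in both vehicle libraries. Fits with this covariate, here and below, therefore cannot tell macrophage content apart from treatment. Lymphocyte markers rose as a list by a median of 0.22 (camera adjusted p = 4.52e-05, and adjusted p = 0.785 with an estimated correlation). All 15 values were positive, though 0 passed over all genes or adjusted over the list alone. Lck, a kinase of T cells, had 0.50 ± 0.16 and 0.92 ± 0.15 CPM. Its log2 fold change was 0.35 with limma and 0.85 with edgeR. The log2(CPM + 1) scale understates changes at such low CPM, so this median cannot be ranked against that of the macrophage markers. Neutrophil markers did not pass (median 0.23, camera adjusted p = 0.0657). Their list mean was at -0.03, -0.05 and 0.83 in JIB-04 replicates 1, 2 and 3, so replicate 3 alone carried the rise. Without JIB-04 replicate 1 camera called them higher at the preset correlation.

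Extracellular matrix and fibrosis genes rose as a list (median 0.27, camera adjusted p = 1.82e-10; adjusted p = 0.785 with an estimated correlation). Of 52 members 48 had positive values, 0 passed over all genes and 2 adjusted over the list alone. Lum, a collagen-binding proteoglycan, had 127 ± 6 CPM in vehicle and 164 ± 5 in JIB-04, and Mmp3, a matrix metalloproteinase, 2.98 ± 0.49 and 12.04 ± 5.69 CPM. The fibrillar collagen genes Col1a1 and Col3a1 had log2 fold changes of 0.41 (SE 0.20) and 0.59 (SE 0.24), with overlapping groups, and 0.24 and 0.35 without vehicle replicate 2. The list mean was at -0.09 in JIB-04 replicate 1, within the vehicle range, against 0.78 and 0.49 in replicates 2 and 3. Without JIB-04 replicate 1 the median was 0.46, and without JIB-04 replicate 2 it was 0.08. Fibroblast markers rose as a list by 0.19 (camera adjusted p = 1.8e-04; adjusted p = 0.785 with an estimated correlation), with 0 of 18 past the threshold over all genes and 1 adjusted over the list alone. JIB-04 replicate 1 was at 0.04 for these markers and replicates 2 and 3 at 0.23 and 0.26, and their median was 0.29 without JIB-04 replicate 1 and 0.12 without vehicle replicate 2. With the macrophage covariate the medians were -0.21 for matrix genes and -0.07 for fibroblast markers.

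The red blood cell markers fell as a list (median log2 fold change -1.22, camera adjusted p = 1.72e-10; adjusted p = 0.785 with an estimated correlation). All 9 values were negative, 0 passed over all genes and 7 passed adjusted over the list alone. Alas2, the erythroid enzyme of heme synthesis, had 106 ± 31 CPM in vehicle and 45.3 ± 15.8 in JIB-04, and Bpgm, which makes bisphosphoglycerate in red cells, 53.6 ± 11.5 and 31.2 ± 6.0 CPM. The beta globin gene Hbb-b1 had 1689 ± 479 and 728 ± 235 CPM, with values identical to those of the Hbb-bs row. The members Hba-a1 and Hba-a2 had identical values too, and are 2 of the 9. The list mean was at -1.51, -0.57 and -1.06 in JIB-04 replicates 1, 2 and 3, and at 0.31 and -0.31 in vehicle.

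Lists of mitochondrial energy metabolism fell by small amounts. All 52 nuclear genes of oxidative phosphorylation had negative values (median -0.11, camera adjusted p = 8.54e-08; adjusted p = 0.785 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Cox7a1, a subunit of cytochrome oxidase, had 193 ± 11 CPM in vehicle and 164 ± 17 in JIB-04. Genes of branched chain amino acid and ketone use fell by a median of 0.17 (17 of 17 negative, camera adjusted p = 4.96e-05; adjusted p = 0.785 with an estimated correlation). Those of the tricarboxylic acid cycle fell by 0.11 (23 of 23 negative, camera adjusted p = 3.2e-04; adjusted p = 0.785 with an estimated correlation). Fatty acid oxidation genes fell by 0.13 (32 of 34 negative, camera adjusted p = 0.00322; adjusted p = 0.815 with an estimated correlation), and Acads, a short chain acyl-CoA dehydrogenase, had 182 ± 3 and 157 ± 14 CPM. In these 3 lists 0 members passed over all genes or adjusted over the list alone. JIB-04 replicate 1 lay at 0.02, 0.03, 0.03 and 0.11 for the 4 lists in this order, against -0.22, -0.31, -0.23 and -0.45 in replicate 2 and -0.14, -0.22, -0.14 and -0.11 in replicate 3. Without JIB-04 replicate 1 the 4 medians were -0.18, -0.25, -0.19 and -0.25, without JIB-04 replicate 2 they were -0.06, -0.10, -0.05 and -0.0002, and without vehicle replicate 2 -0.06, -0.11, -0.06 and -0.04. Without vehicle replicate 1 the tricarboxylic acid cycle and fatty acid oxidation medians were -0.17 and -0.23. Leaving out vehicle replicate 2 or JIB-04 replicate 2 ended the calls of the tricarboxylic acid cycle (camera adjusted p = 0.115 and 0.0633) and fatty acid oxidation lists (0.375 and 0.944). With the macrophage covariate the medians were positive, at 0.07 for oxidative phosphorylation, 0.08 for branched chain, 0.09 for tricarboxylic acid cycle and 0.15 for fatty acid oxidation genes.

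Lists of cardiomyocyte function fell just past the threshold. Sarcomere genes fell by a median of 0.16 (camera adjusted p = 0.0219; adjusted p = 0.815 with an estimated correlation), ion channel and gap junction genes by 0.13 (0.0211), atrial myocyte markers by 0.16 (0.0211) and calcium handling genes by 0.08 (0.0485), the last 3 each with an adjusted p = 0.785 with an estimated correlation. None of their members passed over all genes, and Kcna5 alone passed adjusted over the list alone. Tcap, a protein of the sarcomere's Z disc, had 2236 ± 107 CPM in vehicle and 1637 ± 468 in JIB-04, and Cacna1g, a T-type calcium channel, 140 ± 6 and 118 ± 5 CPM. Myl1, a myosin light chain on the atrial list, had 130 ± 28 and 89.3 ± 4.6 CPM. Each of these 4 calls was lost in at least 2 of the 5 fits with 1 library left out, in some with the median little changed. With no filter on low counts the atrial median was -0.07 (camera adjusted p = 0.0716), and the sarcomere and calcium handling calls were lost too (0.0762 each). The ion channel call was lost at a CPM of at least 1 (0.0556), and with the replicate number as a block the sarcomere (0.0636) and calcium handling calls (median -0.05, 0.107) were lost. Without JIB-04 replicate 2 the median was -0.06 for sarcomere (camera adjusted p = 0.236), -0.05 for ion channel (0.168), -0.13 for atrial (0.0596) and -0.08 for calcium handling genes (0.152). Without vehicle replicate 2 it was -0.07 for sarcomere (0.375), -0.10 for ion channel (0.142) and -0.08 for calcium handling genes (0.0516). Without vehicle replicate 1 it was -0.01 for atrial (0.573) and -0.12 for calcium handling genes (0.121), with sarcomere genes at -0.24 and their call kept. For calcium handling genes it was -0.05 without JIB-04 replicate 3 (0.144) and -0.15 without JIB-04 replicate 1, where the call was kept. Tcap was at -0.26 without JIB-04 replicate 2, against -0.49, and Myl1 at -0.29 without vehicle replicate 1, against -0.52. With the macrophage covariate the medians were 0.02 for sarcomere, 0.04 for ion channel, 0.04 for calcium handling and -0.23 for atrial genes.

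Of the remaining lists, ribosomal protein genes rose by 0.06 (camera adjusted p = 3.36e-05; adjusted p = 0.785 with an estimated correlation) and unfolded protein response genes by 0.10 (camera adjusted p = 0.0187; adjusted p = 0.785 with an estimated correlation). Proteasome, ubiquitin and autophagy genes fell by 0.07 (camera adjusted p = 0.00399; adjusted p = 0.785 with an estimated correlation). In these 3 lists 0 members passed over all genes or adjusted over the list alone. The unfolded protein response call was lost without vehicle replicate 1 (0.0945), JIB-04 replicate 2 (0.109) or JIB-04 replicate 3 (0.407), and the proteasome call without vehicle replicate 2 (0.219). With the replicate number as a block the ribosomal call (median 0.04, camera adjusted p = 0.0823) and the unfolded protein response call (median 0.05, 0.609) were lost. With the macrophage covariate the medians were 0.02 for ribosomal, -0.10 for unfolded protein response and -0.02 for proteasome, ubiquitin and autophagy genes. The median was 0.17 for unfolded protein response genes without JIB-04 replicate 1 and 0.05 without JIB-04 replicate 3. For proteasome, ubiquitin and autophagy genes it was -0.11 without vehicle replicate 1 and -0.01 without vehicle replicate 2.

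**Figure D2:**
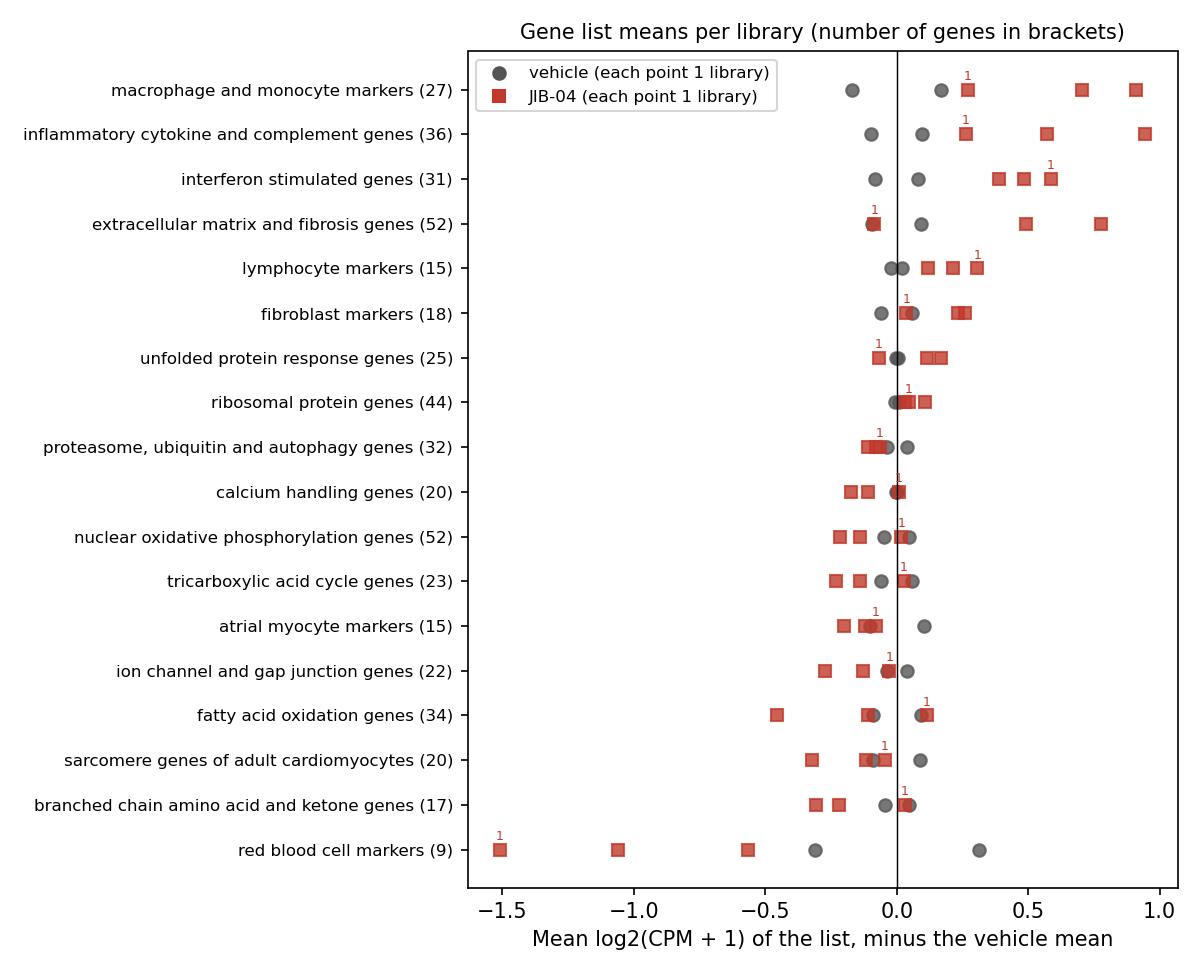
Mean log2(CPM + 1) of the 18 lists that passed camera at its preset correlation, per library and relative to the vehicle mean, with circles for vehicle (n = 2), squares for JIB-04 (n = 3) and a 1 above JIB-04 replicate 1. For extracellular matrix genes JIB-04 replicate 1 lies at -0.09, beside vehicle, and for interferon stimulated genes at 0.59, above both vehicle libraries.

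Fetal and stress genes of hypertrophy did not pass (median 0.07, camera adjusted p = 0.34). The list mean was at -0.191 in JIB-04 replicate 1, against 0.225 and 0.259 in replicates 2 and 3. Without JIB-04 replicate 1 camera called this list higher at the preset correlation. Nppb, which encodes the natriuretic peptide BNP, had 929 ± 103 CPM in vehicle and 1135 ± 343 in JIB-04, and Nppa 1162 ± 276 and 1250 ± 347 CPM. Rcan1, a calcineurin target and regulator, had 258 ± 21 and 362 ± 118 CPM. The log2 fold changes of Nppb and Rcan1 were 0.04 and 0.21 without JIB-04 replicate 2, and 0.50 and 0.70 without JIB-04 replicate 1. The myosin heavy chain genes Myh6 and Myh7 had log2 fold changes of -0.24 (SE 0.42) and 0.00 (SE 0.49), Acta1 0.17 (SE 0.21), Ankrd1 0.09 (SE 0.30), Atp2a2 -0.06 (SE 0.32), Pln -0.20 (SE 0.20), Postn 0.10 (SE 0.37) and Ctgf -0.15 (SE 0.19). Nppa, Myh7, Acta1, Ankrd1, Atp2a2, Postn and Ctgf changed sign when 1 library was left out, for example Nppa to -0.15 without vehicle replicate 2, Acta1 to -0.18 without vehicle replicate 1, Atp2a2 to 0.01 without vehicle replicate 2, Myh7 to -0.13 and Ctgf to 0.03 without JIB-04 replicate 1, and Postn to -0.28 and Ankrd1 to -0.05 without JIB-04 replicate 2.

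Genes for the JmjC demethylases, the enzyme family the inhibitor acts on, had a median log2 fold change of 0.00 over 26 members (camera adjusted p = 0.905). Kdm8 had the smallest p of them, at 3.50 ± 0.11 CPM in vehicle and 4.38 ± 0.16 in JIB-04 (limma adjusted p = 0.752). Kdm3a, Kdm4a, Kdm4b, Kdm4c, Kdm5a, Kdm5b and Kdm6b had log2 fold changes of 0.05, -0.09, -0.08, 0.00, -0.03, 0.04 and -0.08, and the signs of all but Kdm4a turned when 1 library was left out. Without vehicle replicate 2 Kdm4b and Kdm6b were both at 0.03, without JIB-04 replicate 1 Kdm4c and Kdm5b were at -0.08 and -0.04, and without JIB-04 replicate 2 Kdm3a and Kdm5a were at -0.04 and 0.0045. The calcineurin and NFAT pathway list did not pass (median 0.01, camera adjusted p = 0.854).

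The other lists did not pass camera at its preset correlation either. The adjusted p was 0.0657 for immediate early genes, 0.279 for circadian clock, 0.293 for epicardial, 0.339 for cell cycle, 0.399 for adipocyte, 0.429 for xenobiotic and antioxidant and 0.494 for iron handling genes. It was 0.592 for markers of skeletal muscle, lung and thymus, 0.635 for smooth muscle and pericytes, 0.681 for Schwann cells and nerve, 0.706 for glycolysis and 0.843 for endothelial markers. Hypoxia inducible factor targets and growth factor and neurohormonal receptor genes were both at 0.854, and p53 targets at 0.869. For hypoxia targets the median (0.04) and camera's direction differed in sign, as they did for Schwann cell and nerve markers (-0.03). The median and the mean differed in sign for endothelial, antioxidant and receptor genes, and the median of endothelial markers turned from -0.02 to 0.00024 with upper quartile scaling, as that of receptor genes did from -0.01 to 0.00212. Other scalings moved the median of all genes to between -0.00022 and 0.00883, from -0.00924. Without JIB-04 replicate 1 camera called immediate early, epicardial and hypoxia target genes higher at the preset correlation. In that library their list means were at -0.247, -0.159 and -0.198, relative to the vehicle mean.

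The first principal component held 52.2% of the variance and did not separate the groups. JIB-04 replicate 1 lay at -10.4, between the vehicle libraries at -8.23 and -14.1, and JIB-04 replicates 2 and 3 lay at 21.2 and 11.6.

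**Figure D3:**
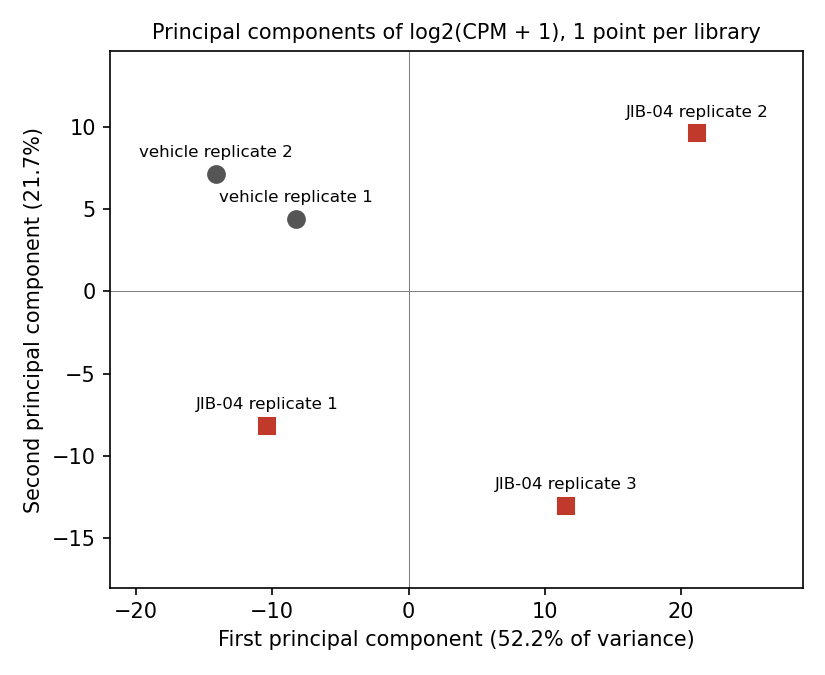
The first and second principal components of log2(CPM + 1), in units of the component score, with 1 point per library, circles for vehicle and squares for JIB-04. JIB-04 replicate 1 (-10.4 on the first component) lies on the side of the vehicle libraries (-8.23 and -14.1), apart from JIB-04 replicates 2 and 3 (21.2 and 11.6).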

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

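The counts of single genes differed between tools and between fits with 1 library left out. They were 0 higher and 0 lower with limma under other scalings, filters, pseudocounts (0.25 and 4, chosen after the data were seen), thresholds and a robust fit, and with edgeR and limma-voom, but 69 and 16 with DESeq2, which tested 15153 genes, and 67 and 16 with DESeq2 on limma's 14414 genes (chosen after the data were seen). With each library left out in turn they ranged from 0 to 27 higher and from 0 to 2 lower, the highest without JIB-04 replicate 1. Where a vehicle library is left out, the other is assumed to vary like the JIB-04 libraries. The cause was not tested. The count of lists past the threshold went from 18 to 0 with an estimated correlation and to 0 with fry, was 13 to 23 with 1 library left out, and 15 to 18 in the other settings. At the preset correlation 9 of the 18 calls held in every setting above that could be run for the list. The other 9 were lost in at least 1, and 0 lists changed direction in these settings. Lymphocyte markers had too few genes at a CPM of at least 1, and red blood cell, atrial and ribosomal lists were left out with the technical lists. The fit with the macrophage covariate was not among these settings. It turned the sign of the median in lists of both kinds. Among them were matrix, fibroblast, oxidative phosphorylation and branched chain genes, whose calls held in the settings above. With the replicate number as a block, 0 genes were higher or lower and 15 lists passed, with Myh7 at -0.0828 and Ankrd1 at -0.0251. Same-numbered libraries had deviations that correlated at -0.133 and -0.135 across genes. The deviations of 2 vehicle libraries mirror each other, so these values cannot show whether the numbers paired the libraries. Of 1608 values for 90 named genes, 1506 kept direction and side of the threshold, 81 passed it and 21 changed sign. With 1 library left out, 33 of the 90 genes changed sign or moved by over 1.5 times. Log2 fold changes with 1 library left out ranged from -0.13 to 0.22 for Myh7, -0.0468 to 0.36 for Ankrd1, -0.18 to 0.53 for Acta1, -0.15 to 0.34 for Nppa, -0.14 to 0.0118 for Atp2a2, -0.28 to 0.45 for Postn and -0.28 to 0.0304 for Ctgf. They ranged from -0.0375 to 0.14 for Kdm3a, -0.18 to 0.0288 for Kdm4b, -0.0775 to 0.0446 for Kdm4c, -0.0797 to 0.0045 for Kdm5a, -0.0408 to 0.0898 for Kdm5b and -0.19 to 0.0264 for Kdm6b. Depth limits genes near the value of 3 reads, 0.0804 to 0.0977 CPM.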

Other observations

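Antigen presentation genes were examined with lists chosen after the single-gene results were seen, as were the genes named in the first 2 paragraphs. The tests with the macrophage covariate, of globin genes apart, of a wrong label and of cell type markers were also chosen after the result was seen, as was the use of the planned left-out-library fits against the interferon rise. MHC class I presentation genes, without those among the highest genes seen, rose as a list (13 of 13 values positive, median log2 fold change 0.17, camera adjusted p = 9.32e-06 over 4 added lists; adjusted p = 0.067 with an estimated correlation). H2-D1, a class I heavy chain, had a log2 fold change of 0.37 (SE 0.08) and B2m, the class I light chain, of 0.30 (SE 0.09). DESeq2 had called H2-D1 higher, so the list was not cleared of genes called in these data. Of 13 members, 0 passed limma's threshold over all genes and 1 passed it adjusted over the list alone. MHC class II genes rose as a list too (7 of 7 positive, median 0.70, camera adjusted p = 6.66e-06; adjusted p = 0.31 with an estimated correlation), with 0 members adjusted over the list alone. Ciita, the class II transactivator, had values of 1.72 and 1.63 CPM in vehicle and 3.09, 2.28 and 4.49 CPM in JIB-04. Both list calls held with each library left out, with a class II median of 0.41 without JIB-04 replicate 3 and 0.99 without JIB-04 replicate 2. In JIB-04 replicate 2 H2-Ab1, H2-Aa and Cd74 were at 24.99, 36.06 and 85.48 CPM, against 25.72, 34.99 and 83.23 CPM in vehicle replicate 1 and 20.74, 29.11 and 70.95 CPM in vehicle replicate 2.

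Without JIB-04 replicate 1, matrix genes stood among the 27 called higher by limma. Fn1, which encodes fibronectin, had a log2 fold change of 0.95 (SE 0.06), Lox, a collagen cross-linking enzyme, 1.19 (SE 0.09), and Spp1, which encodes osteopontin, 2.39 (SE 0.22). With all libraries these were 0.53, 0.65 and 1.75 (limma adjusted p = 0.831, 0.836 and 0.748). In JIB-04 replicate 1 Fn1 was at 107 CPM and Lox at 17.5 CPM, below the vehicle means of 132 and 23.9 CPM. Of the 29 genes called without that library, 9 were also called by DESeq2 with all libraries.

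The rise of interferon stimulated genes was set against 2 explanations. With the macrophage marker mean as a covariate the list was still higher (camera p = 3.33e-27 at the preset correlation), with a median log2 fold change of 0.55 against 0.51 before, although p = 0.0566 with an estimated correlation. The same covariate turned the sign of the median in 10 of the 16 other called lists. These were the matrix, fibroblast, unfolded protein response, sarcomere, calcium handling, ion channel and 4 metabolic lists. It moved inflammatory genes from 0.51 to 0.03. The marker mean was itself at 0.27, 0.70 and 0.91 in JIB-04 replicates 1, 2 and 3, against 0.17 and -0.17 in vehicle. It overlaps with treatment, so the covariate cannot settle macrophage content, which stays open for these lists. The interferon mean went the other way across JIB-04 replicates 1, 2 and 3, at 0.59, 0.48 and 0.39. With 1 library left out the interferon median was 0.39 to 0.55 and the largest camera adjusted p at the preset correlation was 3.8e-13, although with all libraries the call was lost at the estimated correlation of 0.236 (adjusted p = 0.785). At the preset correlation the fits with 1 library left out argue against a single library as the whole cause of the interferon rise. In vehicle the interferon mean went the same way as the marker mean, at 0.082 and -0.082 in replicates 1 and 2. The order of so few JIB-04 libraries therefore cannot decide on macrophage content as its cause, and neither can the covariate. An interferon response to JIB-04 is a hypothesis that stays open, as are other differences between these mice, such as litter, which were not tested.

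The fall of red blood cell markers was not limited to globin genes with shared reads, since the 5 members outside them had a median of -0.76 against -1.23 for the 4 globin genes. Less blood left in the JIB-04 hearts may account for it. The 6 platelet markers tested had a median of -0.0155, with 3 values positive and 3 negative (camera adjusted p = 0.62), and the median turned to 0.11 without JIB-04 replicate 1, to 0.13 without vehicle replicate 1 and to 0.03 without vehicle replicate 2. This cannot be told apart from a lower share of red cells in the blood, because platelet values went both ways and were low. The 3 with negative values, Clec1b, Tubb1 and Ppbp, lay at 0.09 to 0.38, 0.18 to 0.88 and 0.78 to 1.90 CPM. The 3 with positive values lay at 1.68 to 7.15 CPM. At low CPM the log2(CPM + 1) scale understates changes.

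JIB-04 replicate 1 lay beside vehicle on the first principal component. It lay beyond both vehicle libraries, on the side of the other JIB-04 libraries, in 7 of 23 lists called without it, not in 16. The 7 included interferon stimulated genes (0.59) and red blood cell markers (-1.51), and the 16 included matrix genes (-0.09). In this library 29 of 31 interferon stimulated genes were above both vehicle libraries, though these genes vary together. The lists went both ways, so a wrong label cannot be told apart from a response in some lists. Library size does not order the libraries in this way, since JIB-04 replicates 2 and 3 (35650602 and 34782448 reads) lay between the vehicle libraries (37002846 and 32152168), and after thinning to 32152168 reads JIB-04 replicate 1 was still at -10.5. Markers of other cell types did not differ alike between JIB-04 replicates 2 and 3 and replicate 1, from 0.54 (SE 0.04) for macrophages to -0.10 (SE 0.08) for Schwann cells, a gap of 7.03 joint standard errors over genes. These standard errors are over genes, which vary together, not over mice, and the types compared were the highest and lowest of 6. The gap therefore cannot decide on a lower share of cardiomyocytes, and 5 of the 6 types were higher. A difference in response or in disease stage between mice was not tested.

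Fkbp5, Fam107a and Hif3a, among the genes with negative values that the naming rule gave, led to the hypothesis of lower glucocorticoid receptor activity with JIB-04. It was tested on 19 other target genes. These targets fell as a list (median -0.13, 12 of 19 negative, camera p = 0.0125 at the preset correlation, adjusted p = 0.0167; adjusted p = 0.428 with an estimated correlation), as the hypothesis needs. Without Pdk4 and Lcn2, whose values had come up before the test, p was 0.0139 by the same test. The call was lost without JIB-04 replicate 1 (median -0.09, adjusted p = 0.201), and the median was -0.27 without JIB-04 replicate 3 (adjusted p = 1.17e-05) and -0.07 without vehicle replicate 2 (adjusted p = 0.0233). With 0 members past the threshold adjusted over the list alone, the hypothesis stays open.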
